A study of Mus musculus with 47 samples.

How the data were processed

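ChIP-seq peak lists of NMuMG cells were analysed as deposited, with 1 list per library for PHF10, BRG1, ATF3, FOSL2, FOSB and 5 histone marks. Per the labels' protocols, cells for PHF10, BRG1 and ATF3 (14 lists) were crosslinked with disuccinimidyl glutarate and then formaldehyde, and cells for FOSL2, FOSB and the marks with formaldehyde only. The submitters' processing notes name fastp 0.19.5, Bowtie2 2.3.3, MACS3 3.0.0a7, Partek 11.0.24.0325, deepTools 3.5.1 and the mm10 build, without the role or the settings of each. Each list names a single ChIP library and a single input, so peaks were called per library, and no pooling of replicates is recorded.

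Each peak has 4 deposited measurements. The deposited pileup signal is the reads stacked at the peak and was not used for any comparison. The deposited −log10 values are those of the peak caller's p-value and q-value against the input, and served to rank peaks within a list and to filter them. The deposited fold enrichment is the authors' ratio of ChIP over input at a peak. It was used only to describe, rank or filter peaks within a list, except that PHF10 sites of both replicates were ranked by its mean over the replicates. Fold enrichment is not comparable between lists of different depth, so those ranks lean on the replicate with the larger values. The PHF10 and BRG1 lists (8) have no summit and reach down to a −log10 q of 1.00 (q of 0.0996), and the other 24 have summits and reach down to 1.30 (q of 0.0501), so the antibodies were called at different thresholds. In 2 lists, H3K14ac and H3K18ac at 0 h, the file has a header and rounded values, and the others have none. Read totals were not used here, so the depth of each library is unknown and list length cannot be corrected for it. No list of high-signal regions was removed.

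Peaks on chromosomes 1 to 19, X and Y were kept. Groups, times and replicate numbers came from the labels. Peaks were called shared at an overlap of 1 bp. For PHF10, overlapping peaks of the lists compared were joined into sites, and a control site was one called in both replicates. A KO-only PHF10 peak was one in neither control replicate. Shares carry exact Clopper-Pearson intervals at 95%, and ratios of peak numbers carry the interval of the corresponding binomial share. Both cover counting error only, since nearby peaks are not independent and no spread between libraries enters them. The PHF10 peak number at 48 h against 0 h was tested with an exact two-sided permutation test of log2 peak number, and the count of sites was set beside the other splits of the 4 libraries. All other comparisons had 1 library in an arm and no test.

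Overlap of lists was set beside 1000 copies of the first list shifted in a circle along each chromosome, with random placement and shifts of 5 to 20 kb to either side as alternatives. Genes came from the RefSeq table of GRCm38.p6, the assembly that mm10 names, with 21887 protein-coding genes on the chromosomes kept. The table used here holds gene spans without strand. A gene was therefore counted as having a peak within its span or 10 kb to either side, where the plan was the span and 10 kb upstream, and either gene end stood for the transcription start. Exons, introns and untranslated regions were not assigned. A planned count of sequence motifs needed a genome sequence and was not run.

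The gene lists, fixed before the data were examined, held 45 mesenchymal and TGFβ response genes, 35 epithelial genes, 20 AP-1 and ATF genes, 26 SWI/SNF subunit genes, 20 Hippo pathway targets, 20 housekeeping genes and 25 markers of other cell types. Every symbol was found in the table, 4 of them as older names of genes already listed. Each list was placed among 10000 random lists of equal size matched on an H3K4me3 peak within 2 kb of a gene end at 0 h. Genes were named by a rule fixed at the same time. It took members of the mesenchymal, epithelial, AP-1 and ATF and Hippo lists with a peak in 1 arm and none in the other, ranked by the authors' fold, up to 15 per comparison. It also took the 10 strongest peaks found in 1 arm only, named by a gene overlapping them or by the nearest gene end within 100 kb, and 6 genes of the proteins studied. For sites of both replicates the fold is the mean of the highest fold in each. Ovol1 and Spint2 (FOSL2) and Krt19, Ap1m2 and Tgfbi (H3K18ac at 0 h) ranked below the first 15 and were named after their values were seen, because few genes shared their class. The text gives a part of the genes so named, and 1 gene is not reported here.

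Alternatives fixed before the data were examined were peaks with −log10 q of at least 5, peaks with fold of at least 5, all sequences in place of assembled chromosomes, peaks merged within 1 kb, an overlap of 50% of the shorter peak, lists cut to equal length by significance, each PHF10 replicate left out, the replicate number as a block, other backgrounds, gene ends within 2 or 50 kb, and other matching of the random lists. Reducing the KO FOSL2 list to the control length for the gene lists was added after the data were seen. Before the analysis was written, peak numbers, overlaps between pairs of lists and shares near gene ends had been looked through, so the tests of the closing section were chosen with related values known.

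The overlap and site functions were tested on simulated lists. A planted overlap of 60% in 5000 simulated peaks came back as 60.0%, unrelated lists gave 0.893 times the shifted share, and 400 planted gained and 100 planted lost sites were all returned. Of 200 simulated gene lists without excess 4% stood above percentile 95, and of 200 with a planted excess 97% did. The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.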

Results

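Chromatin immunoprecipitation with sequencing was performed in NMuMG cells, an epithelial line from mouse mammary gland that undergoes an epithelial to mesenchymal transition when given transforming growth factor β1 (TGFβ1). Control cells and Pbrm1 knockout (KO) cells received 5 ng/ml TGFβ1 for 24 or 48 h or were left untreated (0 h). PBRM1 is a bromodomain subunit of PBAF, a form of the SWI/SNF chromatin remodeller. The 5 factors profiled were PHF10, a further PBAF subunit, BRG1, the SWI/SNF ATPase encoded by Smarca4, and the bZIP transcription factors ATF3, FOSL2 and FOSB. The 5 histone marks were H3K4me3 (found at promoters), H3K4me1 (found at enhancers and promoter flanks) and the acetylations H3K27ac, H3K14ac and H3K18ac, in control cells at 0 and 48 h.

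The 47 samples comprised 32 libraries with a peak list and 15 inputs used here without one. Control PHF10 had 2 libraries at 0 h and 2 at 48 h, and each of the other groups with a peak list had 1, so that only the PHF10 time comparison had replicates in both arms. The labels do not say whether the replicates came from separate cultures, and the p-value below therefore measures only the spread between these libraries. The lists held 806216 peaks on assembled chromosomes, from 2 (KO FOSB, 0 h) to 158815 (KO PHF10, 48 h). The number of reads behind each list is unknown, and a longer list can reflect more reads as well as more binding. Bracketed ranges are exact Clopper-Pearson 95% intervals, which cover counting error only, and fold enrichment is the authors' value for a peak over input. Positions are in mm10, counted from 1.

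The first comparison asked where PHF10 was found before and after TGFβ1 in control cells. PHF10 peaks shared by both replicates lay at 9694 of 21887 protein-coding genes at 0 h and at 15974 at 48 h (gene body and 10 kb to either side). At 48 h, 9 of 45 genes of the mesenchymal and TGFβ response list had a peak in both replicates and none in either 0 h replicate, as did 5 of 35 epithelial genes, 1 of 20 Hippo pathway targets and 0 of 20 AP-1 and ATF genes. No gene of these 4 lists had the reverse. Of all protein-coding genes, 44.3% had such a shared peak at 0 h and 73.0% at 48 h. The share of all genes under the rule for 48 h only was not computed, so these counts cannot be read as a preference for any list. Ankrd1, a target of the Hippo effector YAP, carried the strongest of these peaks, with a mean fold enrichment of 4.93 (chromosome 19, 36112056 to 36112342).

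Among the mesenchymal genes with PHF10 at 48 h only were Tagln, an actin-binding protein of contractile cells (3.49-fold enrichment; chromosome 9, 45935788 to 45936258), and Sparc, a secreted matrix glycoprotein (3.34). Itgb6, an integrin chain that activates latent TGFβ (3.30), and Thbs1, thrombospondin 1 (3.16), belonged to the same group. So did the type I collagen genes Col1a1 (3.10) and Col1a2 (2.76), Snai2, a repressor of epithelial genes (3.08; chromosome 16, 14705785 to 14706419), and Cd44, the hyaluronan receptor (2.35). The epithelial genes were Cldn4, a tight junction claudin (3.41), the keratins Krt19 (3.31) and Krt18 (3.11), and the ETS factors Elf3 (2.84) and Ehf, where the peaks of the replicates did not overlap each other.

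Of the 22567 sites called in both 48 h libraries and neither 0 h library, the strongest lay 78279 bp from Rspo2, which encodes a secreted Wnt agonist (6.36-fold enrichment; chromosome 15, 42942157 to 42942508). Others of the 10 strongest lay inside Rictor, a subunit of the mTORC2 kinase complex (6.07), 34145 bp from the integrin gene Itgb8 (5.90) and 50240 bp from Cdkn2b, a cyclin-dependent kinase inhibitor (5.83). The strongest of the 64 sites with the reverse pattern lay inside Chl1, which encodes a neural adhesion molecule (32.6-fold enrichment; chromosome 6, 103649059 to 103649295), followed by a site far from genes (13.2; chromosome 2, 98664903 to 98665225) and sites inside the ion channel genes Grin3a (7.96) and Cacna1g (7.76). High-signal regions were not removed, so some of the sites at 0 h only may not reflect PHF10 binding. Of the sites present at 48 h only, 28.7% (28.1 to 29.3) were already called at 24 h. A further 8095 sites were called in all 4 libraries, and 99.9% of them were called at 24 h.

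The lists held 11285 and 14731 peaks at 0 h (replicates 1 and 2), 28011 at 24 h and 43549 and 102434 at 48 h. Mean log2 peak number was 13.65 ± 0.27 (SD, n = 2) at 0 h and 16.03 ± 0.87 (SD, n = 2) at 48 h, a 5.18-fold difference (log2 ratio 2.37). The exact two-sided permutation test of 2 against 2 libraries gave p = 0.33, the smallest p this design allows. The other splits of the 4 libraries gave 868 and 30 sites (by replicate number) and 79 and 358 sites (crossed), against 22567 and 64 for the split by time. Only the split by time sets the 2 longest lists against the 2 shortest, so unequal list length by itself favours a large count there. With only peaks of at least 5-fold enrichment the direction turned (log2 ratio -1.66, with 21 sites at 48 h only and 884 at 0 h only), and with −log10 q of at least 5 the log2 ratio was 0.96. The 48 h replicates differed 2.35-fold in peak number, and 65704 sites were called in 48 h replicate 2 alone. Without 48 h replicate 1 the sites at 48 h only numbered 88504, and without either 0 h replicate the sites at 0 h only numbered 1366 or 1616.

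**Figure D1:**
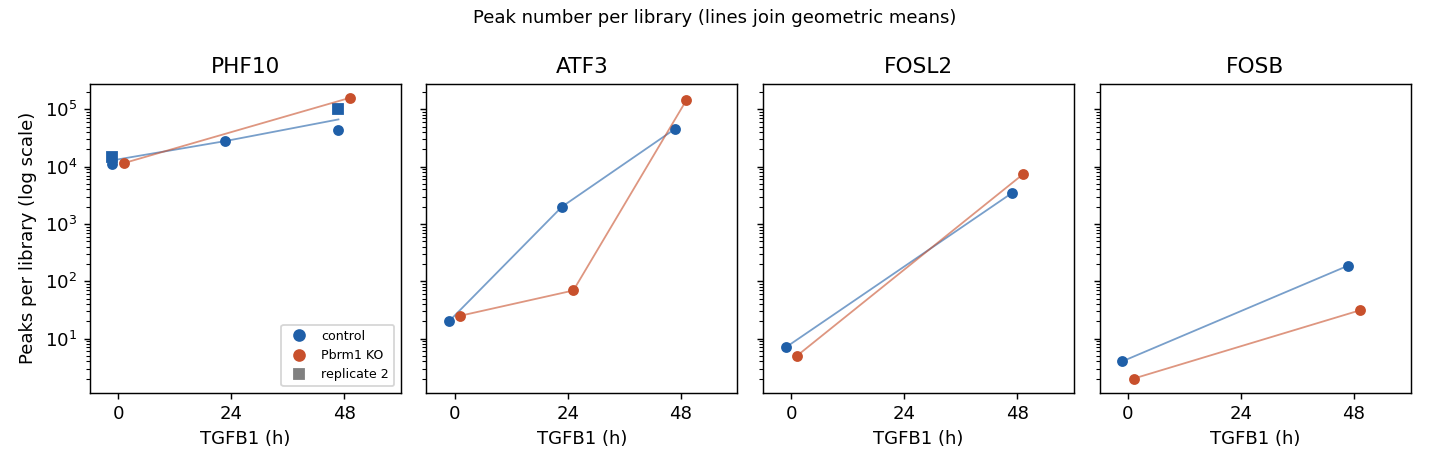
Peaks per library on a log axis against hours of TGFβ1 for PHF10, ATF3, FOSL2 and FOSB, 1 point per library, control in blue and Pbrm1 KO in red, with squares for replicate 2 and lines through the geometric means. ATF3 lists held 2004 peaks in control and 69 in KO at 24 h, and 45716 and 144513 at 48 h.

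The next comparison asked whether PHF10 sites were kept in cells lacking Pbrm1. At 0 h, 95.3% (94.8 to 95.7) of the 8634 sites of both control replicates were called in the KO. Of all replicate 1 peaks, 79.3% lay in the KO list and 76.7% in replicate 2, and of all replicate 2 peaks 65.8% lay in the KO list and 58.8% in replicate 1. Gadd45b, a stress-induced regulator of growth arrest, had a PHF10 peak in both control replicates and none in the KO (6.10-fold enrichment; chromosome 10, 80936508 to 80936783). Tnc, which encodes the matrix protein tenascin C, also had peaks in both control replicates and none in the KO, at positions that did not overlap between the replicates. No other gene of the mesenchymal, epithelial, AP-1 and ATF or Hippo lists differed this way, and none had a peak in the KO alone.

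Among the 10 strongest PHF10 sites found at 0 h in both control replicates and not in the KO were sites at Pcgf3, a subunit of a Polycomb complex (9.37-fold enrichment; chromosome 5, 108461129 to 108461677), at the spectrin gene Sptbn4 (8.65), at the serotonin transporter gene Slc6a4 (8.48) and at Ebf1, a transcription factor of B cell development (8.16). There were 407 such sites. Among the 10 strongest of the 1095 KO peaks in neither control replicate were peaks in Sox13, a SOX transcription factor (7.02; chromosome 1, 133418162 to 133418496), in Bptf, a subunit of the NURF remodeller (7.00), in Mitf, the melanocyte lineage factor (6.66), and 150 bp from the homeobox gene Dlx2 (6.62). The KO list held 11515 peaks, within the 11285 to 14731 of the control replicates.

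At 48 h, 96.9% (96.8 to 97.1) of the 34867 control sites were called in the KO, and no gene of the 4 lists had a PHF10 peak in 1 genotype alone. The KO list held 158815 peaks, of which 55.0% (54.7 to 55.2) lay in either control replicate. The 10 strongest of the other 71541 KO peaks included peaks 20331 bp from Snai2 (7.02; chromosome 16, 14685141 to 14685520) and inside Cnot2, a subunit of the CCR4-NOT deadenylase (6.92). With the KO list and each control replicate cut to equal length, 52.1% of the sites of both cut replicates were called in the cut KO list. With peaks of at least 5-fold enrichment the share was 14.3%. Of the 2000 most significant peaks, 88.1% (86.6 to 89.5) lay within 2 kb of a gene end in control replicate 1, 32.2% (30.1 to 34.2) in control replicate 2 and 26.1% (24.1 to 28.0) in the KO. In this share the control replicates differed by more than replicate 2 and the KO did, whereas at equal list length 48.6% of replicate 1 peaks and 39.9% of KO peaks lay in replicate 2. No test between genotypes was run, since 1 KO library gives no spread within the KO.

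ATF3, a stress-induced bZIP factor and TGFβ target, was compared between genotypes at 0, 24 and 48 h. At 24 h the ATF3 list held 2004 peaks in control and 69 in the KO, a log2 ratio of -4.86 (-5.23 to -4.51), and 10 genes of the 4 lists had a peak in control and none in the KO. The epithelial genes were Tjp1, the tight junction scaffold ZO-1 (5.37-fold enrichment; chromosome 7, 65381938 to 65382149), the epithelial transcription factors Grhl2 (3.93), Ovol2 (3.72) and Ovol1 (2.95), and Cldn4 (3.84). The mesenchymal genes were Hmga2, an architectural chromatin protein (4.25; chromosome 10, 120424044 to 120424355), the fibronectin gene Fn1 (3.57), Pmepa1, a feedback inhibitor of TGFβ signalling (3.55), and the tropomyosin gene Tpm1 (3.49). The Hippo target was F3, which encodes tissue factor (3.20). No gene of the 4 lists had an ATF3 peak in the KO alone at 24 h. For these 4 lists, random lists of equal size held similar numbers of control ATF3 genes at 24 h, with percentile 56.3 for the mesenchymal list (4 genes, random median 4), 88.6 for the epithelial (5, median 3), 36.6 for the Hippo (1, median 1) and 7.52 for the AP-1 and ATF list (0, median 2). The SWI/SNF subunit list stood higher, at percentile 98.2 (6 of 26 genes, random median 2).

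Among the 10 strongest control ATF3 peaks at 24 h outside the KO list were peaks inside Rab3gap1 (8.08; chromosome 1, 127921107 to 127921333), which acts on Rab3 GTPases, and inside the arrestin-like gene Arrdc4 (7.63). Among the 10 strongest of the 51 KO peaks outside the control list were peaks 27634 bp from Efnb2, an ephrin ligand (7.46; chromosome 8, 8589375 to 8589600), and 811 bp from the collagenase gene Mmp1a (7.05). At 0 h, ATF3 lists held 20 peaks in control and 25 in the KO, a difference within counting error (log2 ratio 0.32, -0.59 to 1.25).

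At 48 h the ATF3 list was longer in the KO, with 144513 peaks against 45716 (log2 ratio 1.66, 1.65 to 1.68). ATF3 peaks in control and not in the KO were found at Snai2 (4.13; chromosome 16, 14705844 to 14706061). Peaks in the KO and not in control were found at Ankrd1 (6.28), Cd44 (5.95), Sparc (4.76), Ehf (3.62) and Acta2, smooth muscle actin (2.84). Of the 15233 control peaks outside the KO list, the 10 strongest included peaks 1613 bp from the chemokine gene Cxcl5 (18.8; chromosome 5, 90757295 to 90757684) and inside Zfpm2, a GATA cofactor (19.7). Of the 112580 KO peaks outside the control list, the 10 strongest included a peak 3860 bp from the collagenase gene Mmp13 (9.54; chromosome 9, 7268298 to 7268653). The share of control peaks found in the KO was 66.7% (66.2 to 67.1), 30.8% at equal list length and 6.95% with peaks of at least 5-fold enrichment. At 48 h the direction also turned with that filter (log2 ratio -1.51), while at 24 h the KO list stayed shorter (-3.53).

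FOSL2, a FOS family member of AP-1, was compared between genotypes at 0 and 48 h. FOSL2 peaks were almost absent at 0 h (7 in control, 5 in the KO) and numbered 3444 in control and 7381 in the KO at 48 h, a log2 ratio of 1.10 (1.04 to 1.16). In control cells, FOSL2 peaks at 48 h lay at 12 of 45 mesenchymal and TGFβ response genes, 7 of 35 epithelial genes, 7 of 20 AP-1 and ATF genes and 5 of 20 Hippo targets, against 1 of 20 housekeeping genes. In the KO these counts were 20, 8, 13 and 8, against 3 housekeeping genes. With the KO list reduced to the length of the control list they were 12, 4, 7 and 5, against 1.

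Mesenchymal genes with a FOSL2 peak in the KO and none in control were led by Snai1, the repressor of E-cadherin (11.5-fold enrichment; chromosome 2, 167552748 to 167553166). They included Sparc (8.70), Ccn2, the matricellular growth factor CTGF (8.42; chromosome 10, 24589287 to 24589635), Axl, a receptor tyrosine kinase (7.58), Cd44 (7.58), Zeb2, a repressor of epithelial genes (7.01), and Thbs1 (6.45). Among AP-1 and ATF genes the same held for Jund, an AP-1 partner of FOS proteins (8.89; chromosome 8, 70702828 to 70703124), Fosl1, the FOS family member FRA1 (6.39), Atf2 (6.17) and Atf4, a factor of the integrated stress response (6.08). Amotl1, which binds YAP (9.54), was the strongest Hippo gene, and Tjp1 (8.06), Krt19 (7.30) and the splicing regulator Esrp1 (6.45) were the epithelial ones. A FOSL2 peak in control and none in the KO was found at the epithelial genes Ovol1 (5.46; chromosome 19, 5543410 to 5543661) and Spint2, a protease inhibitor (5.21).

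Of the control FOSL2 peaks at 48 h, 89.0% (87.9 to 90.0) lay in the KO list, which left 379 in control alone and 4314 in the KO alone, and the share was 67.2% at equal list length. The strongest KO peaks outside the control list lay 95814 bp from Ywhaz, a 14-3-3 protein gene (19; chromosome 15, 36898799 to 36899315), and 46583 bp from Egr2, an immediate early transcription factor (17.3). The strongest control peaks outside the KO list lay 9941 bp from the chemokine receptor gene Ackr3 (9.63; chromosome 1, 90225666 to 90226002) and inside Usp43, a deubiquitinase gene (9.37). The KO to control log2 ratio lay between 1.09 and 1.18 under the 4 alternative filters.

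**Figure D2:**
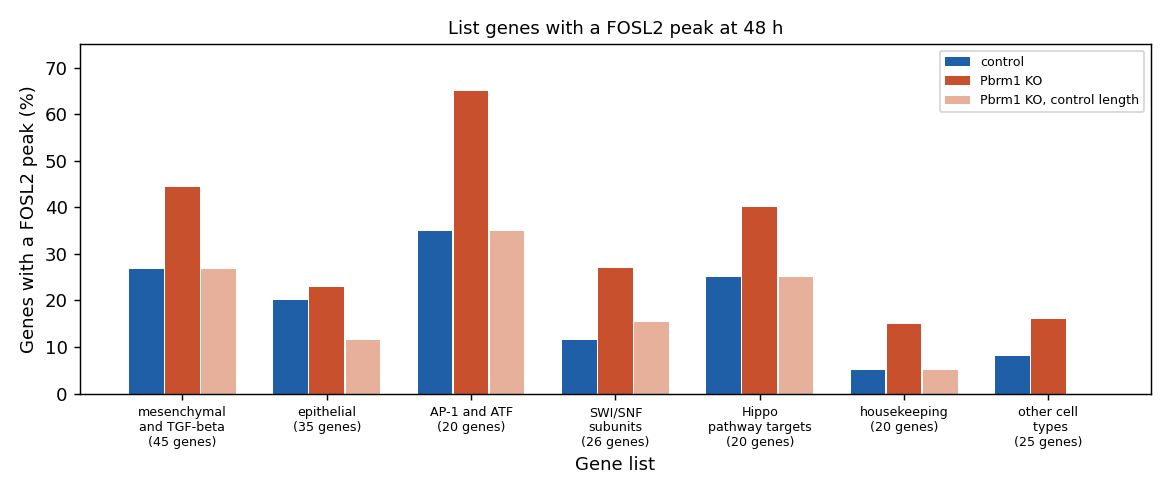
Percent of the genes of each fixed list with a FOSL2 peak at 48 h (y axis, gene body and 10 kb to either side) in control, in Pbrm1 KO and in the KO list reduced to the 3444 peaks of the control list, 1 library per bar. For the mesenchymal list the bars stand for 12, 20 and 12 of 45 genes, and for the AP-1 and ATF list for 7, 13 and 7 of 20 genes.

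FOSB, another FOS family member, had 4 peaks in control and 2 in the KO at 0 h, and 188 and 31 at 48 h (log2 ratio -2.60, -3.20 to -2.05). Control FOSB peaks without a KO counterpart lay at Krt8, a keratin of simple epithelia (8.97-fold enrichment; chromosome 15, 102005287 to 102005638), and at Pmepa1 (5.28). A FOSB peak in the KO and not in control lay at Mafk, a small MAF protein gene (6.14). The strongest control peak outside the KO list lay inside Zcchc2 (9.86), and further ones lay inside the kinase gene Src (7.22) and Rheb, a GTPase that activates mTORC1 (7.22). The lists shared 15 control peaks, and 73.4% (66.5 to 79.6) of control FOSB peaks lay within the control FOSL2 list. FOSB and FOSL2 thus gave ratios of opposite sign at 48 h from 1 library each.

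The histone marks were compared between 0 and 48 h in control cells. H3K4me3 lists were of similar length, with 31657 and 29720 peaks (log2 ratio -0.09, -0.11 to -0.07), and 85.9% of 0 h peaks were found at 48 h. Sparc (5.73-fold enrichment) and Itgb6 (3.70) had H3K4me3 at 0 h only. H3K27ac lists held 20507 and 15962 peaks (log2 ratio -0.36, -0.39 to -0.33). H3K27ac was called at 0 h only at the epithelial genes Krt19 (34.0; chromosome 11, 100145053 to 100145946), Cldn3 (5.20) and Cldn7 (4.98) and at the mesenchymal genes Snai2 (15.2), Sparc (11.6) and Tagln (5.65). It was called at 48 h only at Mmp2, a gelatinase gene (3.37; chromosome 8, 92855359 to 92855611).

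H3K4me1 lists held 20179 and 12863 peaks (log2 ratio -0.65, -0.68 to -0.62), and this direction turned among peaks of at least 5-fold enrichment (3.96). An H3K4me1 peak lay at 50.0% of all protein-coding genes at 0 h and at 43.3% at 48 h. H3K4me1 was called at 0 h only at 11 of 45 mesenchymal genes, such as Smad7, the inhibitory SMAD (5.54; chromosome 18, 75394783 to 75395083), Itgb6 (4.92) and Pmepa1 (3.83), and at 4 of 20 AP-1 and ATF genes, such as Creb1 (4.91) and Bach1 (4.11). It was called at 48 h only at Crem (12.6), Id1, an inhibitor of bHLH factors (5.66), Tgfbr1, a TGFβ receptor (5.46), and the junction genes Dsp (5.65) and Lsr (4.81), among others.

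H3K18ac lists held 13226 and 20415 peaks (log2 ratio 0.63, 0.59 to 0.66), and covered length differed 2.08-fold. Of all protein-coding genes, 24.3% had an H3K18ac peak at 0 h and 45.1% at 48 h. Peaks at 48 h only were found at 9 of 45 mesenchymal, 12 of 35 epithelial, 6 of 20 AP-1 and ATF and 6 of 20 Hippo genes, led by Zeb2 (106-fold enrichment; chromosome 2, 45109159 to 45110340), Tgfbr1 (88.4), Yap1, the Hippo effector (80.5), and Jdp2, an AP-1 repressor (63.0). Krt19 (7.41), Ap1m2, an adaptor subunit of epithelial sorting (6.55), and Tgfbi, a TGFβ-induced matrix protein (4.48), had H3K18ac at 0 h only. H3K14ac lists held 3453 and 35270 peaks (log2 ratio 3.35, 3.30 to 3.40), and 89.4% of 0 h peaks were found at 48 h. H3K14ac at 48 h only was led by Itga5, a fibronectin receptor chain (62.3; chromosome 15, 103365842 to 103367128), Sphk1, sphingosine kinase 1 (61.2), and Maff (52.9). The 0 h H3K14ac and H3K18ac lists were deposited in another layout than all other lists, with a header and rounded values, so time and file handling cannot be separated for these 2 marks.

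Factor lists were next set against each other and against the marks in control cells. PHF10 sites at 0 h lay almost wholly in chromatin with H3K4me3 and H3K27ac, with 99.6% (99.4 to 99.7) in H3K4me3 and 95.9% (95.4 to 96.3) in H3K27ac peaks. Of the peaks of the 0 h replicates, 65.5% and 66.0% lay within 2 kb of a gene end. Of the PHF10 sites, 54.0% (52.9 to 55.0) lay in BRG1 peaks, 27.2 times the share of circularly shifted sites and 13.3 times that of sites shifted by 5 to 20 kb, and the share was 30.2% at equal list lengths. ATF3 peaks at 48 h lay in H3K4me3 (62.2%), H3K14ac (67.6%) and PHF10 sites (61.5%, 61.0 to 61.9; 21.4 times the circularly shifted share and 5.73 times that after shifts of 5 to 20 kb). FOSL2 peaks at 48 h lay mostly outside these marks, with 2.82% (2.29 to 3.43) in H3K4me3, 4.30% (3.64 to 5.03) in H3K27ac and 12.7% (11.6 to 13.9) in H3K18ac, and 3.08% lay in ATF3 peaks. Before treatment, BRG1 was already present at 50.5% (48.8 to 52.2) of the positions of later control FOSL2 peaks and at 77.1% (70.5 to 82.9) of those of FOSB. Of 30 pairs of factor and mark, 28 exceeded the highest of 1000 circularly shifted sets, and the exceptions were FOSL2 and FOSB with H3K4me1. Against shifts of 5 to 20 kb 27 did, since FOSL2 with H3K4me3 only equalled the highest shifted share (2.82%). Of the H3K4me1 peaks at 48 h, 52.2% lay within 2 kb of a gene end, near the 50% of H3K4me3. Low overlap with this H3K4me1 list therefore says little about enhancers far from gene ends. The BRG1 share of PHF10 sites was 3.41% with −log10 q of at least 5, and the PHF10 share of ATF3 peaks was 6.92%.

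**Figure D3:**
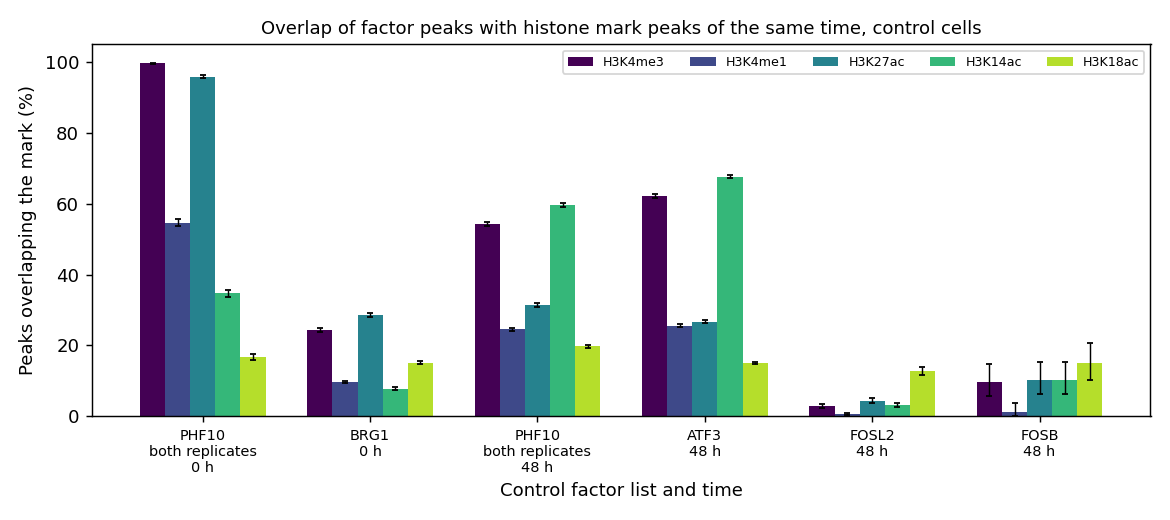
Percent of factor peaks in control cells that overlap a histone mark peak of the same time by at least 1 bp (y axis), for each factor list and time (x axis), 1 color per mark, with exact 95% binomial intervals as error bars. PHF10 at 0 h overlaps H3K4me3 at 99.6% of its sites and FOSL2 at 48 h at 2.82%.

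The fixed gene lists were placed among 10000 random lists of equal size, matched on H3K4me3 at a gene end at 0 h. For control FOSL2 at 48 h the mesenchymal list stood at percentile 99.8 (12 genes, random median 5), the AP-1 and ATF list at 99.7 (7 genes, random median 2), the Hippo targets at 96.9 and the epithelial list at 94.7. With gene ends within 2 kb the mesenchymal list stood at percentile 88.5 (2 genes) and the Hippo targets at 36.1 (0 genes), and matching on gene length as well put the Hippo targets at 86.8. For the same FOSL2 list the SWI/SNF subunit genes stood at 52.9, the markers of other cell types at 51.8 and the housekeeping genes at 20.6. PHF10 sites at 0 h lay at all 26 genes of the SWI/SNF subunit list (percentile 100.0, random median 17), 16 of 20 Hippo targets (99.7) and 28 of 45 mesenchymal genes (64.2). They lay at 11 of 20 housekeeping genes (26.9) and at 7 of 25 markers of other cell types (16.4, but 90.7 with gene ends within 50 kb). BRG1 at 0 h lay at 20 of 20 Hippo targets (percentile 100.0), 37 of 45 mesenchymal genes (98.2, but 76.9 with gene ends within 50 kb) and 30 of 35 epithelial genes (99.3). It also lay at 17 of 20 housekeeping genes (92.5, and 97.1 with matching on gene length), so a high percentile for BRG1 was not particular to the pathway lists. H3K27ac at 48 h lay at 7 of 25 markers of other cell types, at percentile 0.265, and at 14 of them, at percentile 18.1, with gene ends within 50 kb. These percentiles describe single lists and are no test between conditions.

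The genes of the proteins studied were looked up in every list. Pbrm1 (chromosome 14, 31019138 to 31121592) had PHF10 peaks within its span or 10 kb to either side in every PHF10 list, and ATF3 peaks at 48 h in both genotypes. At 0 h the strongest PHF10 peak lay beyond the span in control replicate 1 (12.5, from 31130944) and in the KO (6.04, from 31130848). In control replicate 2 the strongest lay at the other end of the gene (3.74, from 31018936), so these values belong to different positions. A FOSL2 peak near Pbrm1 was called at 48 h in the KO (8.14) and not in control. Phf10 (chromosome 17, 14944994 to 14961260) had a FOSL2 peak at 48 h in control (6.74) and in the KO (8.90). Fosl2 (chromosome 5, 32136472 to 32157840) had its own FOSL2 peak in control (9.63) and in the KO (10.4), and Fosb (chromosome 7, 19302696 to 19310118) had one in the KO alone (5.05). Atf3 (chromosome 1, 191170296 to 191183333) carried ATF3 peaks at 48 h in control (12.7) and in the KO (8.63) and none at 0 or 24 h. Smarca4 (chromosome 9, 21616106 to 21704230) had 1 PHF10 peak in each 0 h list, and at 48 h 5 and 14 in the control replicates and 18 in the KO. Peak lists of these antibodies do not measure loss of PBRM1, so the genotype rests on the labels.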

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

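The tests of explanations in this part were chosen after the results they bear on had been seen, and the filters on fold and q were planned.

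The KO to control ratio of ATF3 peak number had opposite signs at the 2 treated times, while the number rose from 24 to 48 h in both genotypes. The log2 ratio of KO over control was -4.86 at 24 h (2004 peaks in control, 69 in the KO) and 1.66 at 48 h (45716 and 144513), a difference of 6.52. The difference itself was not tested, because each group had 1 library. Among peaks of at least 5-fold enrichment the 48 h ratio was -1.51, the same sign as at 24 h, while with −log10 q of at least 5 the signs stayed opposite (0.10, 0.08 to 0.12, at 48 h and -2.94 at 24 h). Opposite signs were looked for only where both counting intervals excluded 0, a condition set after the values were seen, which left out the sparse 0 h pairs.

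The few KO peaks of ATF3 at 24 h could be the strongest of the control sites, reached by a poorer library. Outside regions already called at 0 h, 12 of 63 KO peaks lay in the control list, or 19% (10.2 to 30.9), against the 80% or more set for that reading. This argues against the KO peaks being mainly a part of the control list. It cannot decide on a poorer library, which could also give calls elsewhere. Of KO peaks 4.35% (0.906 to 12.2) lay within 2 kb of a gene end, against 17.0% (15.3 to 18.7) in control. The control peaks themselves might be calls at random positions near the threshold. Of them 27.6% (25.7 to 29.7) lay in the control 48 h ATF3 list. The highest of the circularly shifted sets reached 3.34%, which argues against all of them being at random positions. The test cannot decide on a part of them, since 1450 of the 2004 control peaks lay outside the 48 h list. Shifts over short distances were not used for this share. In the same way, 43.5% (31.6 to 56.0) of the 69 KO peaks at 24 h lay in the longer KO 48 h ATF3 list. The highest of their circularly shifted sets reached 15.9%, so the KO peaks were not all at random positions either. A difference in library quality and an effect of Pbrm1 loss on ATF3 at 24 h both stay open, and the second was not tested apart from the first.

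The longer PHF10 and ATF3 lists of the KO at 48 h may reflect a library batch rather than genotype, and the labels leave room for this. The file of control PHF10 48 h replicate 2 carries the number of the other replicate in its name, and its input is spelled as in the KO 48 h list, so that the replicate numbers at 48 h are in doubt. At equal list length 39.9% of KO PHF10 peaks lay in control replicate 2, less than the 48.6% of control replicate 1, which taken alone goes against a batch shared by replicate 2 and the KO, yet the KO lay nearer to replicate 2 than to replicate 1 (35.4%), which goes with one. The share of strong peaks near gene ends (26.1% in the KO, 32.2% in replicate 2, 88.1% in replicate 1) goes with such a batch too, and this second criterion was added after the first had come out against it, so batch and genotype cannot be told apart here. A property of the KO 48 h chromatin or input common to both antibodies also stays open: 75.2% of KO-only ATF3 peaks lay in the KO PHF10 list (7.92 times the shifted share), below the 98.7% of ATF3 peaks found in both genotypes. Of the KO-only ATF3 peaks, 43.3% (43.0 to 43.6) also lay in the list of control PHF10 48 h replicate 2. A part of these positions was thus called in control cells too.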

How the results depend on the processing

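Reducing the KO FOSL2 list to the control length for the gene lists was chosen only after the result was seen, and all other alternatives were planned. Over 35 results and 158 alternatives, 84 stayed, 69 moved and 5 turned direction, and the cause was not tested except where named. A result stayed if it lay within the interval or factor of 1.5 set for it. The PHF10 peak number ratio was judged by its sign alone, so its change from log2 2.37 to 0.96 with −log10 q of at least 5 counts as stayed. The factor of 1.5 for covered length, the use of the interval of the share for ratios to background, and the choice of gene-list results in this tally were set with the tables in view. The tally depends on them. Read depth is unknown, intervals cover counting error only, and the stricter filters act unevenly because enrichment scales differ between lists. All sequences in place of assembled chromosomes moved none of 26 results, and random placement in place of circular shifts none of 3. FOSL2 at 0 h had no value with fold of at least 5, since no KO peak remained, and the motif count was not run.

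With fold of at least 5, 5 results turned direction: the PHF10 peak number ratio (log2 -1.66), the ATF3 ratio at 48 h (log2 -1.51), H3K4me1 peak number (log2 3.96) and covered length (log2 4.84), and H3K4me3 covered length (log2 -0.048). PHF10 sites at 48 h only numbered 21 and at 0 h only 884. Control sites found in the KO were 87.1% (PHF10, 0 h), 14.3% (PHF10, 48 h), 6.95% (ATF3, 48 h) and 90.2% (FOSL2, 48 h). The log2 ratio of KO over control was -3.53 for ATF3 at 24 h and 1.18 for FOSL2 at 48 h. The mark ratios were -0.25 (H3K4me3), -0.26 (H3K27ac), 3.21 (H3K14ac) and 0.56 (H3K18ac). The BRG1 share of PHF10 was 0.0880% and the PHF10 share of ATF3 0.0365%.

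With −log10 q of at least 5, the PHF10 ratio was 0.96, PHF10 sites at 48 h only numbered 718 and at 0 h only 190, and control sites found in the KO were 92.8% (PHF10, 0 h), 46.1% (PHF10, 48 h) and 31.8% (ATF3). The ATF3 log2 ratio was -2.94 at 24 h and 0.10 at 48 h, mark ratios were -0.46 (H3K4me1), 3.46 (H3K14ac) and 1.17 (H3K18ac), and the shares were 3.41% (BRG1 of PHF10) and 6.92% (PHF10 of ATF3). Merging peaks within 1 kb gave an ATF3 log2 ratio of 1.50 at 48 h, 67.3% of control ATF3 sites in the KO, mark ratios of -0.60 (H3K4me1), 3.26 (H3K14ac) and 0.58 (H3K18ac) and a PHF10 share of ATF3 of 59.9%. With an overlap of 50% of the shorter peak, shares were 96.3% (PHF10 48 h in the KO), 63.7% (ATF3 in the KO), 50.4% (BRG1 of PHF10) and 60.6% (PHF10 of ATF3).

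At equal list lengths, control sites found in the KO were 96.2% (PHF10, 0 h), 52.1% (PHF10, 48 h), 30.8% (ATF3) and 67.2% (FOSL2), the BRG1 share of PHF10 was 30.2% and the PHF10 share of ATF3 43.7%. The KO FOSL2 counts were then 12 mesenchymal and 7 AP-1 and ATF genes, which by construction comes from a shorter list. Against shifts of 5 to 20 kb the BRG1 share of PHF10 was 13.3 times and the PHF10 share of ATF3 5.73 times the background.

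Leaving out each PHF10 replicate in turn gave 23194 to 88504 sites at 48 h only (88504 without 48 h replicate 1), 83 to 1616 sites at 0 h only (1366 and 1616 without either 0 h replicate, 505 without 48 h replicate 2), control sites found in the KO of 65.8% to 79.3% at 0 h and 88.0% to 92.5% at 48 h, a BRG1 share of PHF10 of 39.4% to 41.4% and a PHF10 share of ATF3 of 58.8% to 90.2%. A single list then stands for the sites of both replicates, so the counts grow by construction. The log2 PHF10 ratio lay between 1.76 and 2.99. The replicate block gave the same mean log2 ratio, 2.37 ± 0.60 (SD, n = 2), with an exact two-sided sign-flip p of 0.5, the smallest that 2 pairs allow. The numbers share only a number in the labels, and with the pairs crossed the SD was 1.14.

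For control FOSL2 at 48 h, gene ends within 2 kb gave 2 mesenchymal (percentile 88.5), 2 epithelial (92.8) and 3 AP-1 and ATF genes (99.7) and 0 Hippo targets (36.1), and within 50 kb 21 (100.0), 15 (99.7), 12 (100.0) and 8 (97.3). In the same order, unmatched random lists gave percentiles 99.9, 97.5, 99.9 and 97.9, and lists matched on gene length as well 99.7, 97.7, 100.0 and 86.8.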

Other observations

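All tests in this part were chosen after the results they bear on had been seen, and the shared regions were defined then as well.

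FOSL2 peaks found in both genotypes at 48 h differed from those of 1 genotype in where BRG1 had been before treatment. In the KO list, 52.9% (51.1 to 54.7) of the 3067 peaks shared with control lay at a BRG1 peak of control cells at 0 h, against 33.9% (32.5 to 35.3) of the 4314 KO-only peaks, which include those at Snai1, Ccn2, Jund and Fosl1. In the control list the shares were 52.5% (50.7 to 54.2) and 34.8% (30.0 to 39.9), so peaks of 1 genotype lay less often at BRG1 positions on both sides. H3K18ac at 48 h showed the same order in the KO list, with 17.6% (16.2 to 19) of shared and 10.2% (9.31 to 11.1) of KO-only peaks. In the control list the H3K18ac shares were 13.2% (12.0 to 14.4) and 8.97% (6.29 to 12.3), with overlapping intervals. The shared KO peaks also had a higher median enrichment (9.36 against 6.45), and the shares were not compared at equal enrichment.

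Several of the strongest mark peaks at 0 h only lay far from genes. Of the 10 strongest H3K14ac peaks at 0 h only, 4 lay on chromosome 9 between 3015204 and 3038199, more than 100 kb from any protein-coding gene of the table. A PHF10 site at 0 h only lay nearby (chromosome 9, 3006695 to 3007670), and high-signal regions were not removed. Such peaks may therefore not reflect a histone mark or PHF10 binding. A peak inside Vav3, a guanine nucleotide exchange factor gene, led the H3K18ac list (28.2-fold enrichment; chromosome 3, 109513823 to 109514115) and ranked after the first in the H3K14ac list (14; 109513827 to 109514056). The strongest H3K14ac peaks at 48 h only lay at the gene ends of Abl2, a tyrosine kinase (90.2; chromosome 1, 156558438 to 156559623), and Prmt1, an arginine methyltransferase (83.1; chromosome 7, 44985647 to 44986449). The strongest H3K18ac peak at 48 h only lay inside Usp42, a deubiquitinase gene (194; chromosome 5, 143731495 to 143732529).

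A set of 13081 regions was common to 5 control lists: H3K4me3 and H3K4me1 at 0 h, PHF10 at 24 h, and ATF3 and H3K14ac at 48 h. One hypothesis is that such regions come down with any antibody. PHF10 covered 43.0% and 53.7% of them at 0 h and 75.5% and 97.3% at 48 h (replicates 1 and 2). H3K4me3 at 48 h covered 96.1%, H3K4me1 at 48 h 66.7% and H3K27ac 64.3% at 0 h and 40.9% at 48 h. BRG1 covered 19.4% and H3K18ac at 48 h 18.7%, which argues against recovery with any antibody. H3K18ac at 0 h covered 2.90% (2.62 to 3.21), but that list was deposited in another layout. Another is that they are promoters alone. Of the regions, 50.2% (49.4 to 51.1) lay within 2 kb of a gene end, below the 80% set for that reading. The regions were taken from the H3K4me3 peaks at 0 h, of which 47.6% lay there, and promoters inside genes were not counted. The 80% would turn away that whole H3K4me3 list as well, so this test cannot decide on promoters. The 5 lists came from both crosslinks, so neither crosslink alone accounts for the set. Promoters, open chromatin and the day of the experiment stay open, and no biological explanation other than promoters was tested.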
